A study of Mus musculus with 15 samples.

How the data were processed

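The deposited values were the authors' log2 signals from robust multi-array averaging (RMA), computed by the submitters with Partek 6.5; the RMA version and its settings were not given. All values were used as deposited, with no further scaling, from 1 table of 45141 probe sets on 15 one-colour arrays. The 104 control probe sets were left out, as were 15692 probe sets without a listed gene and 551 listed with several genes. Of the 28898 probe sets listed with 1 gene, 28689 were given their current symbol through the gene identifier in the GRCm38.p6 annotation and 209 kept the listed symbol. Each of the 17097 genes was represented by the probe set with the highest mean log2 signal over the 15 arrays, a choice that mattered for the 7180 genes with more than 1 probe set. The 95th percentile of 23 nonspecific control probe sets, 4.77, served as the background level, and a group mean under it was read as signal that could not be told from background.

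Groups were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes in a single one-way fit over the 5 groups of 3 arrays (10 residual degrees of freedom, 2.54 prior degrees of freedom). Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene was said to rise, fall or change when its adjusted p was below 0.05. A second count asked in addition for a log2 difference of at least 1, a 2-fold change. Differences are given in log2 units with the standard error of the fit, group means with the standard deviation of 3 arrays. The standard errors come from a spread shared by the 5 groups. The number of arrays limits the precision. All p-values measure the spread between these samples, since the labels state no batch, sex or pairing and do not say whether the arrays of a group came from separate animals.

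The 6 comparisons, the test, the rule for named genes, the gene lists and the alternatives below, except the additional ones named as such, were chosen before the data were examined. The named genes were, for Myc primary against Shh tumours, the 12 largest rises and 12 largest falls, and for the other comparisons the 6 largest of each, among genes past both thresholds whose arrays did not overlap between groups, without predicted genes. To these came Myc, Mycn, Mycl, Atoh1, Gli1, Ptch1, Cdkn2c and Trp53 in every comparison, and up to 4 members of each list with the smallest adjusted p. Trp53 had no probe set assigned to it alone and could not be measured. Genes, families and arrays named outside this rule are said to have been chosen after their values were seen.

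The 27 lists held 362 different genes, of which 317 were measured. Hhip, Sfrp1, Atoh1, Nrl, Gad1 and Emx2 were shared between lists, so those lists overlap. The lists covered the Shh pathway, granule neuron progenitors, granule neurons, neural stem cells, astroglia, the oligodendrocyte lineage, GABAergic and Purkinje neurons, forebrain neurons, microglia and macrophages, lymphocytes, endothelial and mural cells, fibroblasts and meninges, and erythroid cells. The others were Myc targets of ribosome biogenesis, the cell cycle, pluripotency, photoreceptors, markers of the human medulloblastoma groups Shh, WNT, group 3 and group 4, interferon and MHC class I, immediate early and stress genes, p53 targets, glycolysis and hypoxia, the Notch pathway, and sex-linked genes. Each list was tested with limma's camera at a preset correlation of 0.01 and again with the correlation estimated from the data by camera, each adjusted over the 27 lists of a comparison. Member calls were counted with p adjusted over all genes and adjusted over the list alone.

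The alternatives were the mean of a gene's probe sets, every probe set tested by itself, dim genes left out (no group mean above the 25% quantile of all values, 3.7, which removed 2109 genes and kept 14988), cyclic loess, arrays centred on their median gene, a fit on only the 6 arrays of a comparison (4 residual degrees of freedom), an intensity trend with robust variance, array weights, and each array left out in turn. Chosen after seeing the data were a fit without the 3 arrays that stood apart from their group (Myc primary 3, GFP-negative 3 and Myc secondary 1) and a term for the 2 runs of sample title numbers. The earlier run held the Myc primary, the Shh and the GFP-negative 1 and 2 arrays, and the later run held GFP-negative 3, the GFP-positive and the Myc secondary arrays. The robust variance used statmod 1.5.0, and the figures used Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.

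The fit was tested on simulated data with known differences placed on the spread of these arrays, pooled over the 5 groups. For Myc primary against Shh tumours it recovered 55.9% of genes shifted by log2 1, 84.8% of those shifted by 2 and 93.9% of those shifted by 3; 13 of its 186 calls were unshifted genes. For Myc secondary against Myc primary tumours it recovered 55.9%, 90.9% and 98.5%. In each of the 6 comparisons camera called the shifted list and none of the unshifted ones. The simulated genes were drawn independently of each other. The simulation therefore does not test the preset correlation on lists whose members vary together, as the oligodendrocyte lineage list did (estimated correlation 0.82). Each simulated gene also had the same spread in all 5 groups, so the recovered shares need not hold for groups of unequal spread. Real arrays correlated at 0.995 within the GFP-positive group and at 0.97 to 0.974 within the Myc primary group.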

Results

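RNA from 15 mouse samples was hybridised to 1-colour Affymetrix HT_MG-430_PM arrays, 1 array per sample, in 5 groups of 3. The Myc primary tumours grew in the cerebral cortex of nude mice after implantation of cerebellar cells that lacked Cdkn2c and Trp53, carried an Atoh1-GFP reporter and had been infected with Myc. The Myc secondary tumours grew from transplanted sphere cultures of such tumours. The Shh tumours were spontaneous medulloblastomas of mice without Cdkn2c and with Trp53 deleted through Nestin-Cre. The GFP-positive and GFP-negative groups were sorted, by the fluorescence of the Atoh1-GFP reporter, from cerebella at postnatal day 6; Atoh1 is the transcription factor that specifies granule neuron progenitors. The labels of these 6 samples call them spontaneous tumour, whereas the study's design text calls them sorted cerebellar cells. The design text was followed, and the conflict remained open. Tumour cells had been purified on a Percoll density gradient, a step that removes debris and part of the non-tumour cells.

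Log2 signals of the deposited probe sets ran from 2.66 to 14.1. Where a group mean lay below background, the size of a difference is set by the floor of the array. Array medians over all 45141 probe sets, including those not assigned to a gene, lay between 4.637 and 4.89, close to the background level of 4.77. Pearson correlations between arrays of a group, across genes, were 0.97 to 0.974 for Myc primary tumours, 0.98 to 0.988 for Shh tumours, 0.963 to 0.983 for GFP-negative cells, 0.995 for GFP-positive cells and 0.962 to 0.994 for Myc secondary tumours. GFP-negative 3 had the narrowest interquartile range, 2.989 log2, against 3.33 to 3.782 on the other arrays. Myc secondary 1 had a mean correlation of 0.962 with the other arrays of its group. In Myc primary 3, markers of the oligodendrocyte lineage lay 3.05 log2 above their mean over the 15 arrays (median of 11 genes), against -0.40 and -1.44 in Myc primary 1 and 2. Fibroblast and meningeal markers lay 2.54 above their mean in Myc primary 3, against -0.25 and 0.64. Xist, transcribed from the inactive X chromosome of females, read 12.38 in Shh 3 against 6.86 and 5.01 in Shh 1 and 2, and 5.60 in GFP-positive 1 against 11.84 and 11.89 in GFP-positive 2 and 3. Eif2s3y, a gene of the Y chromosome, read 8.83 ± 0.60 in GFP-positive cells. In GFP-negative cells it read 9.05 ± 0.29, where Xist read 11.34 ± 0.34. High Xist in the sorted cells thus did not mark RNA of females alone.

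**Figure D1:**
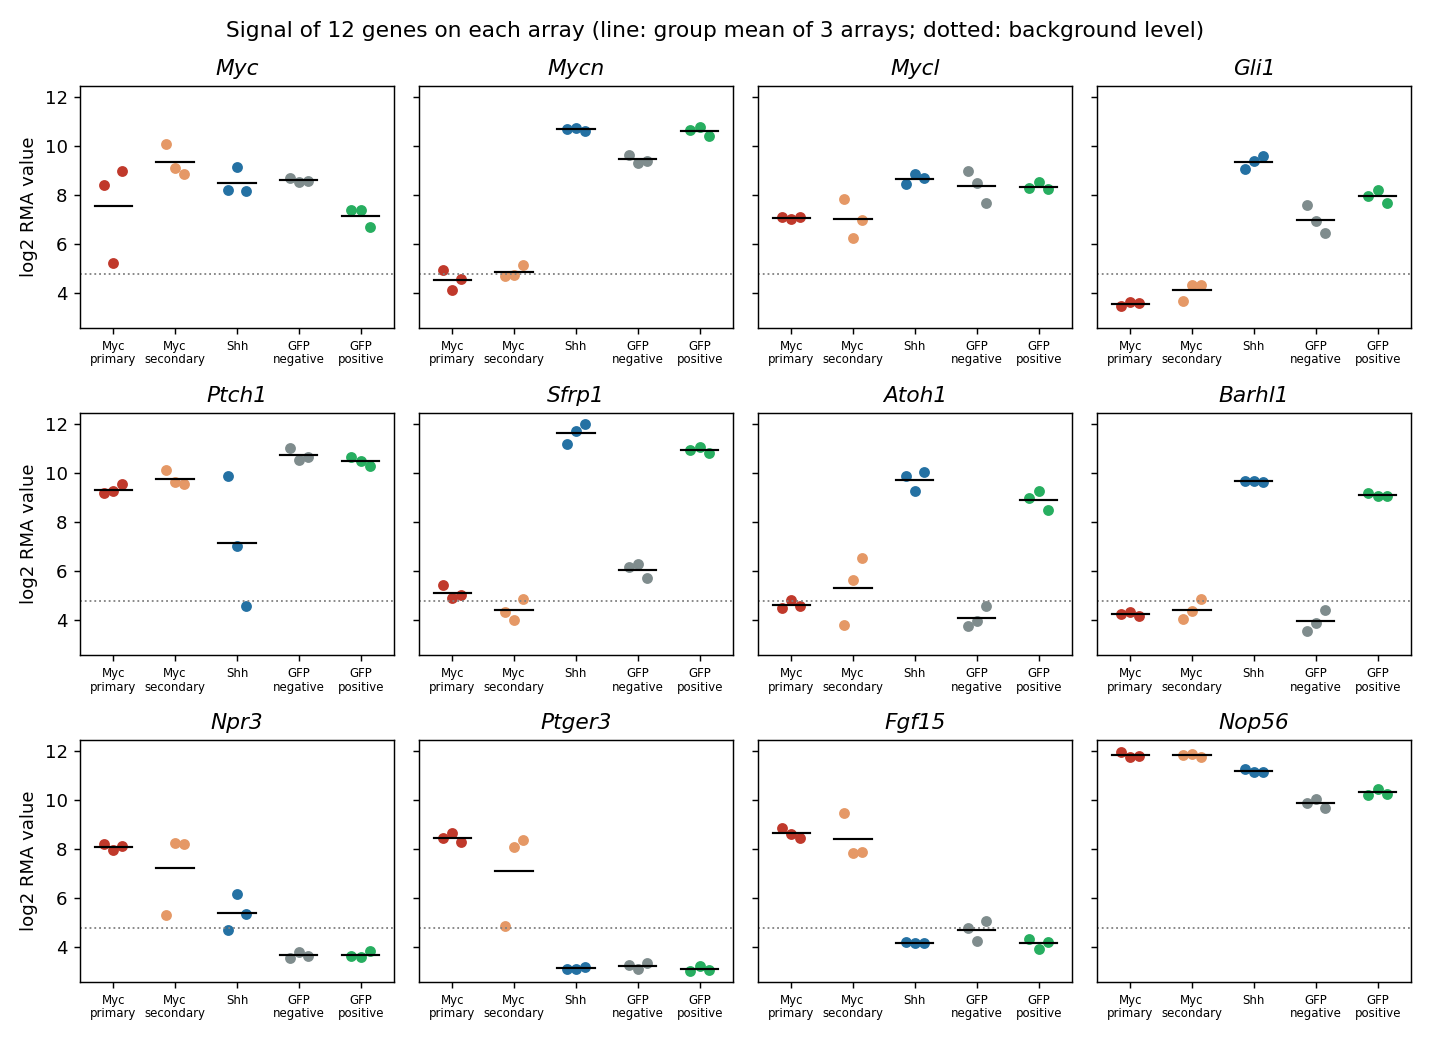
Log2 signal of 12 genes on each of the 15 arrays, with 1 panel per gene, points for arrays, a line for each group mean and a dotted line for the background level of 4.77. Mycn, Gli1, Sfrp1, Atoh1 and Barhl1 read higher in Shh tumours than in Myc primary tumours, Npr3, Ptger3 and Fgf15 the other way round, and Myc primary 2 read 5.21 for Myc.

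The first comparison asked how the Myc primary tumours differed from the Shh tumours, 2 models of medulloblastoma subgroups. Genes of the Shh pathway and of granule neuron progenitors were lower in the Myc tumours. Gli1, the transcription factor and readout of Shh signalling, fell by 5.77 ± 0.27 (standard error; 3.57 ± 0.10 against 9.34 ± 0.27, SD, n = 3; adjusted p = 5.3e-08). Mycn, a Myc-family gene induced by Shh in progenitors, fell by 6.16 ± 0.20 (adjusted p = 7.4e-09) on the probe set used, whereas 1 of its 3 probe sets was called higher and their mean gave -0.29 (adjusted p = 0.18). Sfrp1, a secreted Wnt modulator used to recognise human Shh medulloblastoma, fell by 6.54 ± 0.25, and Atoh1 by 5.11 ± 0.52 (adjusted p = 4.5e-05). Genes of ribosome biogenesis and glycolysis were higher in the Myc tumours, with Ldha, lactate dehydrogenase, up by 1.64 ± 0.21 (adjusted p = 0.00025). As lists they had an adjusted p = 0.049 and an adjusted p = 0.2 with an estimated correlation, so that the call of the glycolysis list was lost. Myc itself read 7.54 ± 2.04 against 8.49 ± 0.55 and did not pass (-0.95 ± 0.74, adjusted p = 0.44); Myc primary 2 read 5.21, and without it the direction turned (0.21, adjusted p = 0.79). Myc was read by 1 probe set, whose position relative to the introduced Myc sequence was not given, and Trp53 had no probe set of its own and was not measured.

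Among the 12 largest rises were Ptger3, a prostaglandin E receptor (5.34 ± 0.65), Umodl1 (5.21 ± 0.42), Nefh, the heavy neurofilament (adjusted p = 3.7e-06), Igfbp2, which binds insulin-like growth factors (4.96 ± 0.41), and Car12, a carbonic anhydrase (4.94 ± 0.41). The others were Arhgap6 (4.68 ± 0.64), Fkbp11 (4.67 ± 0.31), Ydjc (4.64 ± 0.22), Pdk1, a kinase that restrains pyruvate dehydrogenase (4.58 ± 0.38), Ptgds, prostaglandin D synthase (4.52 ± 0.53), the growth factor gene Fgf15 (4.48 ± 0.35) and Mgp, matrix Gla protein (4.46 ± 0.74). For all of these except Igfbp2, Ptgds and Mgp the Shh group mean lay below background, so the size of the difference is set by the floor of the array. The 12 largest falls were Tbata (-6.63 ± 0.25), Sfrp1, Mycn, Gli1, Mdk, the growth factor midkine (-5.65 ± 0.68), Cadps2 (-5.53 ± 0.51), Barhl1, a homeobox gene of granule neuron progenitors (-5.45 ± 0.22), Cavin2 (-5.42 ± 0.39), Atoh1, Ntrk3, the neurotrophin 3 receptor (-5.10 ± 0.22), Tshz2 (-5.09 ± 0.34) and Slc17a6, a vesicular glutamate transporter (-4.98 ± 0.54). For Mycn, Gli1, Barhl1, Atoh1, Tshz2 and Slc17a6 the Myc group mean lay below background, so the sizes and order of these falls are set by the floor too. Mycl fell by 1.60 ± 0.36 (adjusted p = 0.0089). Ptch1, the Shh receptor, read 9.90, 7.03 and 4.56 in the Shh tumours and did not pass (2.17 ± 0.89, adjusted p = 0.12), nor did Cdkn2c (0.22 ± 0.10, adjusted p = 0.17), which read below background in both groups.

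Of the 11 measured Shh pathway genes 8 fell and 3 did not pass (9 fell and 1 rose adjusted over the list alone), with a median difference of -2.33 (adjusted p = 2.5e-11, and adjusted p = 0.021 with an estimated correlation). Besides Gli1, Mycn and Sfrp1 these included Boc, a Shh co-receptor (-3.43 ± 0.26), and Hhip, a Shh antagonist and target (-2.33 ± 0.67, adjusted p = 0.032). Granule neuron progenitor genes fell in 6 of 9 cases (6 of 9 adjusted over the list alone). The median was -1.64 (adjusted p = 3.4e-07, and adjusted p = 0.046 with an estimated correlation), among them the transcription factor genes Meis1 (-2.22 ± 0.42) and Zic2 (-1.64 ± 0.34). Granule neuron genes fell in 7 of 16 cases (9 adjusted over the list alone). The median was -0.76 (adjusted p = 1.1e-05, and adjusted p = 0.049 with an estimated correlation), with Etv1 at -2.49 ± 0.28, Reln, the secreted signal reelin, at -1.75 ± 0.32 and the neuronal splicing factor Rbfox3 at -1.02 ± 0.16. Markers of human Shh medulloblastoma fell in 4 of 5 cases (4 adjusted over the list alone). The median was -4.31 (adjusted p = 9.6e-06, and adjusted p = 0.046 with an estimated correlation); Pdlim3 fell by 4.31 ± 0.68.

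Myc targets of ribosome biogenesis rose in 26 of 32 cases (28 adjusted over the list alone), with a median of 1.08 (adjusted p = 9e-17, and adjusted p = 0.049 with an estimated correlation). Examples were Rrp9 (1.84 ± 0.21) and Nolc1 (1.30 ± 0.15), which act in ribosomal RNA processing, Phb, prohibitin (1.27 ± 0.15), and the sterol-regulated Tmem97 (1.83 ± 0.16). Glycolysis and hypoxia genes rose in 10 of 16 cases (12 adjusted over the list alone). The median was 1.54 (adjusted p = 3.4e-08, and adjusted p = 0.2 with an estimated correlation), among them the enzymes Tpi1 (1.81 ± 0.20) and Pgk1 (1.40 ± 0.16). Of the 27 cell cycle genes 3 rose, with Ccne1, cyclin E1, at 1.54 ± 0.22 (median 0.04, mean 0.08, test pointing down, adjusted p = 0.93).

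Fibroblast and meningeal markers rose in 4 of 10 cases (7 adjusted over the list alone). The median was 1.66 (adjusted p = 0.00051, and adjusted p = 0.43 with an estimated correlation), with Col3a1, a fibrillar collagen, at 2.72 ± 0.66; it read 9.26 ± 1.82 in the Myc tumours, of which Myc primary 3 was the highest for 9 of the 10 markers, and without it the list median was 0.86. Endothelial and mural markers rose in 4 of 14 cases (6 adjusted over the list alone). The median was 0.75 (adjusted p = 0.0049, and adjusted p = 0.78 with an estimated correlation), with Vwf, von Willebrand factor, at 1.78 ± 0.41; within the Myc group all 14 were highest in Myc primary 3, and without it the median was 0.34 (adjusted p = 0.19). Immediate early and stress genes fell in 4 of 13 cases (8 adjusted over the list alone). The median was -1.10 (adjusted p = 0.0003, and adjusted p = 0.45 with an estimated correlation), with Jun at -2.09 ± 0.51. Within the Myc group all 13 were highest in Myc primary 3, and without it the median was -1.58. On only the 6 arrays the calls of Jun (adjusted p = 0.11) and of Col3a1 (adjusted p = 0.093) ended, and that of Jun also ended without Shh 2 (adjusted p = 0.069). Without Myc primary 1, Myc primary 2, Shh 2 or Shh 3 the call of Hhip ended.

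The remaining lists were not called. Neural stem cell genes moved both ways, with Sox9 at -3.29 ± 0.25, Lhx2 at -2.61 ± 0.51 and Cd44 at 1.88 ± 0.41 (1 rose and 2 fell of 14, adjusted p = 0.29). Astroglia had a median of 0.77 (1 rose and 3 fell of 14, adjusted p = 0.84), the oligodendrocyte lineage of 1.40 (1 rose and 1 fell of 11, adjusted p = 0.49; 0.28 without Myc primary 3, where all 11 were highest within its group) and GABAergic and Purkinje neurons of -0.10 (1 fell of 12, adjusted p = 0.46). Pdgfra, the receptor of oligodendrocyte precursors, fell by 2.90 ± 0.45. Forebrain neuron genes fell in 3 of 10 cases (adjusted p = 0.29). None of the 15 microglia and macrophage markers (adjusted p = 0.91), 9 lymphocyte markers (adjusted p = 0.84) or 4 sex-linked genes (adjusted p = 0.93) passed in limma, and 0 of these had an unadjusted p below 0.05. Among 4 erythroid genes (adjusted p = 0.85), 5 human WNT markers (adjusted p = 0.55) and 5 human group 4 markers (adjusted p = 0.84) no gene passed either, with 1, 2 and 0 at an unadjusted p below 0.05. Human group 3 markers gave 2 rises and 1 fall among 4 (adjusted p = 0.84): Npr3, the natriuretic peptide clearance receptor, rose by 2.70 ± 0.61. Gabra5, a GABA receptor subunit, rose by 2.20 ± 0.58, a call that ended without Myc primary 1 (1.59) or 3 (1.82) and without Shh 2 (2.19) or 3 (2.12). Pluripotency (2 rose of 13, adjusted p = 0.49), photoreceptor (1 fell of 12, adjusted p = 0.64), interferon and MHC class I (1 fell of 13, adjusted p = 0.16), p53 target (1 rose and 2 fell of 14, adjusted p = 0.55) and Notch genes (1 rose and 2 fell of 11, adjusted p = 0.93) were not called. Examples in these were Oasl2, an interferon-induced gene (-2.01 ± 0.26), Eda2r (-1.86 ± 0.34) and Perp (1.98 ± 0.39), both p53 targets, and Hey1, a Notch target (-2.56 ± 0.34). Gabra6 and Nrl, counted as falls of the granule neuron, photoreceptor and group 3 lists, Fezf2 of the forebrain list and Car9, counted as a rise of the glycolysis list, lay below background in both groups. Median and mean differed in sign for erythroid (0.18 and -0.18) and sex-linked genes (-0.22 and 0.08), and for Notch genes the median was 0.27 while the test pointed down.

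In total 2701 of 17097 genes changed, 1447 higher and 1254 lower in the Myc tumours, 1562 of them at least 2-fold (773 higher and 789 lower); 4972 had an unadjusted p below 0.05. For 36.5% of genes the 3 values of each group did not overlap, against 10% by chance. By map position in the GRCm38.p6 assembly, a grouping chosen after the values were seen, 106 of the 604 genes of chromosome 14 were lower and 11 higher, while 130 of the 659 genes of chromosome 13 were higher and 21 lower. The count was 1795 without Shh 2 and 4073 without the 3 arrays that stood apart.

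**Figure D2:**
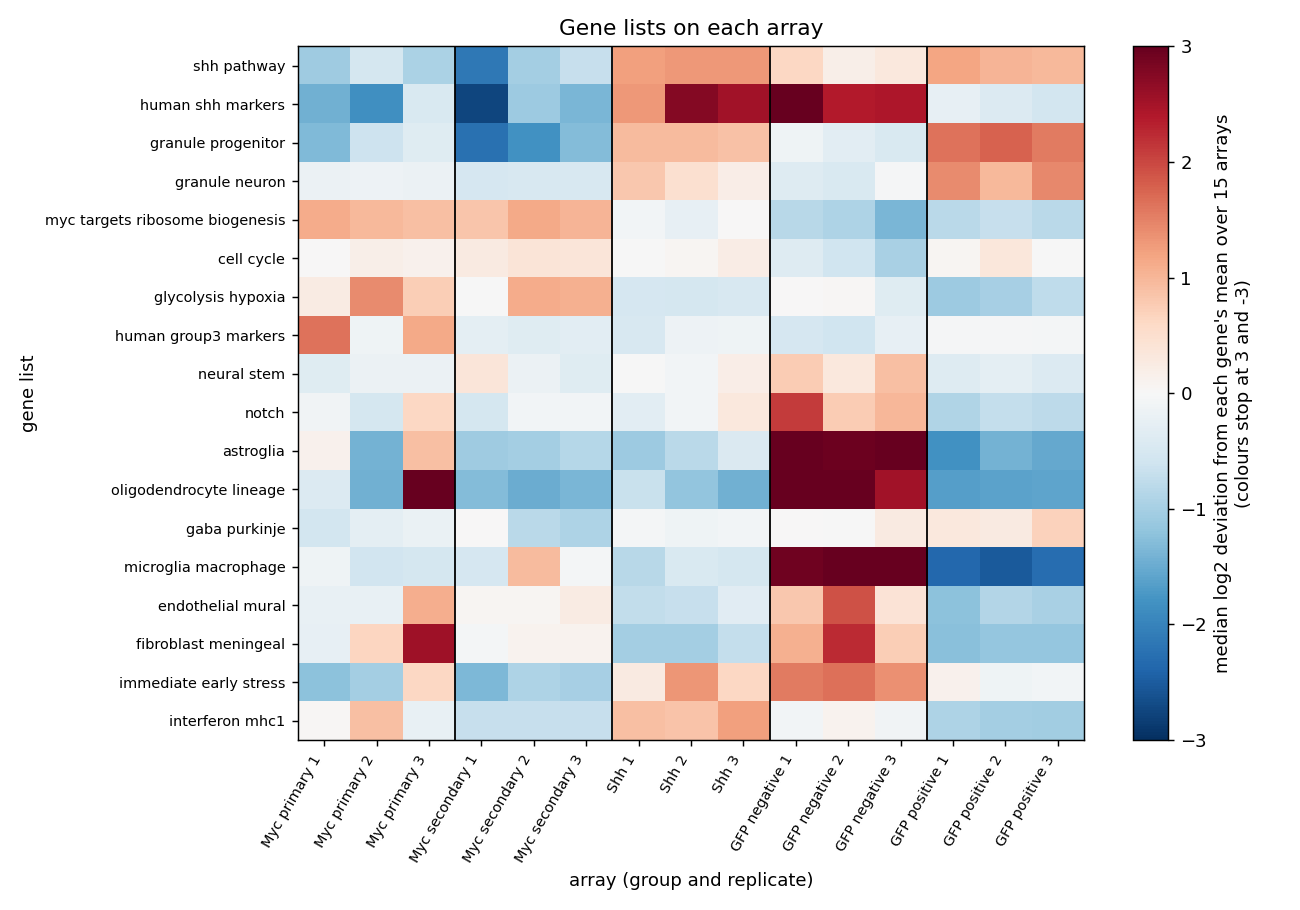
Median log2 deviation of the members of selected gene lists from their mean over the 15 arrays, for each array. Myc targets lay at 0.90 to 1.11 in Myc primary tumours and 0.84 to 1.14 in Myc secondary tumours, at -0.24 to 0.02 in Shh tumours and at -1.38 to -0.70 in the sorted cells.

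The second comparison asked what transplantation of cultured cells changed in the Myc tumours. Few genes differed between secondary and primary tumours. Dlx1, a homeobox gene of forebrain interneurons, rose by 3.15 ± 0.15 (7.10 ± 0.31 against 3.95 ± 0.08, SD, n = 3; adjusted p = 5.7e-07). Pou3f3, a neural POU-domain factor, fell from 7.54 to 3.54, below background (adjusted p = 0.00058), Cdk6, a kinase of the G1 phase, by 3.24 ± 0.37 (adjusted p = 0.0034) and Clec10a, a lectin of macrophages, by 3.22 ± 0.31 (adjusted p = 0.00098). These p-values rest on the spread shared by the 5 groups. On only the 6 arrays of this comparison 1 of the 123 changed genes was still called. At most 1 of the gene calls named for it therefore held there. The genes that define the models gave no call: Myc read 9.36 ± 0.65 against 7.54 ± 2.04 (1.82 ± 0.74, adjusted p = 0.33; 0.66 without Myc primary 2), and the differences were 0.32 ± 0.20 for Mycn, 0.69 ± 0.52 for Atoh1, 0.53 ± 0.27 for Gli1, -0.05 ± 0.36 for Mycl, 0.45 ± 0.89 for Ptch1 and 0.43 ± 0.10 for Cdkn2c (adjusted p = 0.079).

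The other large rises were Rlf (3.54 ± 0.56), Htr3a, a serotonin receptor (2.93 ± 0.60), Smg6, an endonuclease of nonsense-mediated decay (2.58 ± 0.40), Ramp2 (2.44 ± 0.47) and Taf15, an RNA-binding protein (2.14 ± 0.27). The other large falls were Arhgap6 (-4.73 ± 0.64), B3gnt5 (-3.72 ± 0.50) and Scg2, secretogranin II (-3.67 ± 0.54). Rlf in primary tumours, and Arhgap6, B3gnt5 and Scg2 in secondary tumours, had means below background, so these sizes are set by the floor. Sox9, a neural stem and glial factor, fell by 1.67 ± 0.25, Zic4 by 2.67 ± 0.53 and Sema6a by 2.05 ± 0.38. Of 13 interferon and MHC class I genes 2 fell (6 adjusted over the list alone), the chemokine gene Cxcl10 (-3.08 ± 0.57) and the interferon-induced Ifit3 (-2.08 ± 0.43); the list median was -0.85 (adjusted p = 4.2e-05, and adjusted p = 0.71 with an estimated correlation). Run and group are confounded except for GFP-negative 3, so a term for the run of title numbers is estimated from that 1 array, which had the narrowest interquartile range. This term ended the calls of Rlf (0.95), Htr3a (2.17), Smg6 (0.88), Ramp2 (0.27), Taf15 (1.73), Arhgap6 (-4.41), B3gnt5 (-3.59), Sema6a (-0.88), Zic4 (-2.04), Cxcl10 (-3.56) and Ifit3 (-2.32).

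Lists were also called through shifts in which single members did not pass. For 11 oligodendrocyte lineage genes the median was -1.80 (adjusted p = 0.00014, and adjusted p = 0.71 with an estimated correlation), with Mbp, myelin basic protein, at -2.59 ± 0.88 (adjusted p = 0.23); its 3 primary values were 8.43, 6.12 and 11.30. All 11 were highest in Myc primary 3 within its group, and without it the median was -0.46 (adjusted p = 0.032). For 14 astroglia genes the median was -0.88 (adjusted p = 0.0062, and adjusted p = 0.71 with an estimated correlation), and the call ended without Myc primary 1 (-0.48) or Myc primary 3 (-0.29). Fibroblast and meningeal genes had a median of -0.61 (adjusted p = 0.047, and adjusted p = 0.83 with an estimated correlation), which was 0.01 without Myc primary 3; the call also ended without Myc secondary 1 (-0.53), 2 (-0.72) or 3 (-0.66). Cell cycle genes had a median of 0.16 (27 genes, adjusted p = 0.00014, and adjusted p = 0.71 with an estimated correlation), with Aurka, a mitotic kinase, at 0.74 ± 0.25. For 15 microglia and macrophage genes the median was 0.52 (adjusted p = 0.00088, and adjusted p = 0.71 with an estimated correlation), with C1qa, a complement subunit, at 0.93 ± 0.42; without Myc secondary 2 it was 0.23 (adjusted p = 0.25). Granule neuron progenitor genes had 1 fall among 9, Zic4 (5 adjusted over the list alone), and a median of -0.67 (adjusted p = 0.024, and adjusted p = 0.71 with an estimated correlation), a call that ended without Myc primary 3 (-0.69), Myc secondary 1 (-0.56) or 2 (-0.62). Of the 5 lists with no passing member, the oligodendrocyte, astroglia, fibroblast, cell cycle and microglia lists had 4, 4, 2, 5 and 1 members at an unadjusted p below 0.05. Median and test or mean differed in sign for GABAergic and Purkinje (0.04 and mean -0.05), erythroid (0.02, test down), Myc target (-0.02, test up), pluripotency (-0.05, test up) and sex-linked genes (-0.11, test up).

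Between secondary and primary tumours 123 genes changed, 44 higher and 79 lower, 95 of them at least 2-fold (28 higher and 67 lower), and 2137 had an unadjusted p below 0.05. Values of the groups did not overlap for 17.7% of genes, against 10% by chance. The count was 271 without Myc primary 1, 47 without Myc primary 3, 25 without Myc secondary 2 and 60 without Myc secondary 3; it was 284 without the 3 arrays that stood apart, 860 with the run term, of which only 16 were among the 123, and 1 on only the 6 arrays. Centring the arrays on their median gene gave a median of all genes of 0.30, against -0.03, and 274 genes, of which 77.7% were higher, against 35.8%; the means of probe sets gave 264 (59.8% higher), every probe set 426 (66.2% higher) and array weights 581.

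The GFP-positive and GFP-negative groups, taken as sorted cerebellar cells although their labels read spontaneous tumour, served as reference populations. GFP-positive cells carried the granule neuron lineage genes, with Atoh1 higher by 4.84 ± 0.52 (8.92 ± 0.39 against 4.09 ± 0.42, SD, n = 3; adjusted p = 1.9e-05), Barhl1 by 5.15 ± 0.22 (adjusted p = 1.8e-08) and Neurod1, a proneural factor, by 4.36 ± 0.42. As lists, granule neuron progenitor and granule neuron genes had an adjusted p = 0.054 and an adjusted p = 0.058 with an estimated correlation. Glial, immune and vascular genes were lower in GFP-positive cells, and none of these lists kept its call with an estimated correlation (adjusted p = 0.054 for astroglia, 0.28 for the oligodendrocyte lineage, 0.058 for microglia and 0.22 for endothelial genes). Aqp4, the water channel of astrocytes, was lower in GFP-positive cells by 8.40 ± 1.05 (adjusted p = 6.5e-05), C1qb, a complement subunit made by microglia, by 8.01 ± 0.34 and Mbp by 6.82 ± 0.88. Mycn was higher in GFP-positive cells by 1.16 ± 0.20 (adjusted p = 0.00097) and Gli1 by 0.95 ± 0.27 (adjusted p = 0.019); without GFP-negative 3 the latter was 0.68 (adjusted p = 0.072), and its call also ended without GFP-negative 2 (0.93), GFP-positive 1 (0.94) or GFP-positive 2 (0.82). Myc read 7.15 ± 0.41 against 8.60 ± 0.08 and did not pass (-1.46 ± 0.74, adjusted p = 0.18); Mycl, Ptch1 and Cdkn2c gave -0.03 ± 0.36, -0.25 ± 0.89 and 0.05 ± 0.10.

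The largest rises were Nrn1, neuritin (7.28 ± 0.61), Uncx (7.06 ± 0.54), Cadps2 (6.75 ± 0.51), Mab21l1 (6.53 ± 0.93), Sstr2, a somatostatin receptor (6.38 ± 0.35), and Sphkap (6.07 ± 0.48). The largest falls, beside Aqp4 and C1qb, were Gdf10 of Bergmann glia (-8.05 ± 0.40), Ednrb, an endothelin receptor (-7.88 ± 0.51), Ly86 of myeloid cells (-7.71 ± 0.62) and Tnc, tenascin C (-7.64 ± 0.46). For all of these rises except Mab21l1 the GFP-negative mean lay below background, and for all of these falls the GFP-positive mean did. Those sizes are set by the floor of the array. Granule neuron progenitor genes rose in 7 of 9 cases (7 adjusted over the list alone). The median was 2.15 (adjusted p = 1.1e-06, and adjusted p = 0.054 with an estimated correlation), with Nhlh1 at 3.58 ± 0.26 and Insm1 at 2.15 ± 0.23. Granule neuron genes rose in 8 of 16 cases (8 adjusted over the list alone). The median was 1.25 (adjusted p = 1.6e-05, and adjusted p = 0.058 with an estimated correlation), with Rbfox3 at 3.54 ± 0.16 and Tubb3, neuronal tubulin, at 3.54 ± 0.30. Cell cycle genes rose in 19 of 27 cases (22 adjusted over the list alone). The median was 0.72 (adjusted p = 1.2e-08, and adjusted p = 0.2 with an estimated correlation), with E2f1 at 1.87 ± 0.13. Shh pathway genes gave 5 rises and 1 fall among 11 (5 and 1 adjusted over the list alone). The median was 0.95 (adjusted p = 0.027, and adjusted p = 0.28 with an estimated correlation); the fall was Hhip (-4.98 ± 0.67), and the call ended without GFP-negative 3 (0.68). Myc targets gave 8 rises and 1 fall among 32 (8 and 1 adjusted over the list alone). The median was 0.27 (adjusted p = 0.027, and adjusted p = 0.5 with an estimated correlation), a call that ended without GFP-negative 3 (0.22) or GFP-positive 2 (0.20) and with cyclic loess (0.05).

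Astroglia genes were lower in GFP-positive cells in 13 of 14 cases (14 adjusted over the list alone). The median was -5.36 (adjusted p = 2.6e-13, and adjusted p = 0.054 with an estimated correlation), with Aldh1l1 at -6.75 ± 0.39 and the lipid carrier Apoe at -6.70 ± 0.40. Microglia and macrophage genes fell in 15 of 15 cases (15 adjusted over the list alone). The median was -6.03 (adjusted p = 6.8e-20, and adjusted p = 0.058 with an estimated correlation), with Ctss, cathepsin S, at -7.44 ± 0.38. Oligodendrocyte lineage genes gave 10 falls among 11 (10 adjusted over the list alone). The median was -5.08 (adjusted p = 1.3e-05, and adjusted p = 0.28 with an estimated correlation), with Olig1 at -7.10 ± 0.88; the rise was Pdgfra (3.69 ± 0.45). Endothelial and mural genes fell in 12 of 14 cases (13 adjusted over the list alone). The median was -2.50 (adjusted p = 1.2e-08, and adjusted p = 0.22 with an estimated correlation), with the tight junction gene Cldn5 at -5.22 ± 0.60. Fibroblast and meningeal genes fell in 7 of 10 cases (8 adjusted over the list alone). The median was -2.65 (adjusted p = 2.4e-05, and adjusted p = 0.22 with an estimated correlation), with Col3a1 at -6.56 ± 0.66. Erythroid genes fell in 2 of 4 cases (2 adjusted over the list alone). The median was -1.30 (adjusted p = 0.011, and adjusted p = 0.2 with an estimated correlation), with Alas2 of haem synthesis at -2.08 ± 0.19. Neural stem cell genes gave 6 falls and 1 rise among 14 (8 and 1 adjusted over the list alone). The median was -0.73 (adjusted p = 0.0023, and adjusted p = 0.054 with an estimated correlation), with Sox2 at -4.70 ± 0.66. Notch genes gave 7 falls and 1 rise among 11 (7 and 2 adjusted over the list alone). The median was -2.42 (adjusted p = 0.0012, and adjusted p = 0.2 with an estimated correlation), with the receptor Notch1 at -4.94 ± 0.45 and the targets Hes5 at -3.17 ± 0.33 and Hes1 at -3.36 ± 0.46.

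Immediate early and stress genes fell in 5 of 13 cases (7 adjusted over the list alone). The median was -1.51 (adjusted p = 0.00059, and adjusted p = 0.36 with an estimated correlation), with the orphan receptor Nr4a1 at -4.39 ± 0.46. Glycolysis and hypoxia genes fell in 8 of 16 cases (9 adjusted over the list alone). The median was -0.66 (adjusted p = 0.0036, and adjusted p = 0.41 with an estimated correlation), with Pdk1 at -2.96 ± 0.38. Interferon and MHC class I genes fell in 5 of 13 cases (5 adjusted over the list alone). The median was -0.48, and 0.02 on centred arrays (adjusted p = 0.0039, and adjusted p = 0.37 with an estimated correlation), with Cxcl10 at -5.37 ± 0.57. Ptf1a, which specifies GABAergic neurons of the cerebellum, fell by 4.96 ± 0.23 in a list that was not called (3 rose and 1 fell of 12, adjusted p = 0.52). Other members of the list read higher in GFP-positive than in GFP-negative cells, such as Lhx1 (10.62 against 7.78) and Gad1 (9.28 against 8.39). The rise of Gad2 and the fall of Col1a2 lay below background in both groups. For pluripotency genes the median was 0.06 while mean (-0.29) and test pointed down, and for forebrain neuron genes the median was -0.00 and the mean 0.28. Between the sorted populations 4505 genes changed, 2149 higher and 2356 lower in GFP-positive cells, 2726 of them at least 2-fold (950 higher and 1776 lower), with 6016 at an unadjusted p below 0.05. Groups did not overlap for 42.8% of genes, against 10% by chance. The run term, estimated from GFP-negative 3 alone, kept 2999 of the 4505 calls. Centring gave a median of all genes of 0.54, against 0.04, and 9128 genes, 82.3% of them higher against 47.7%, and array weights gave 7225.

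Myc primary tumours were set against GFP-negative and GFP-positive cells to ask what set them apart from these 2 populations. Across genes, their arrays had mean correlations of 0.923 to 0.926 with GFP-positive cells and 0.879 to 0.909 with GFP-negative cells. Against GFP-negative cells, Myc targets of ribosome biogenesis were higher in 31 of 32 cases, with Srm, spermidine synthase, up by 2.85 ± 0.21 (12.01 ± 0.01 against 9.15 ± 0.56, SD, n = 3; adjusted p = 1e-06) and the nucleolar Nop56 by 1.99 ± 0.12; the list had an adjusted p = 0.099 with an estimated correlation. Mycn was lower by 4.92 ± 0.20 (adjusted p = 1.3e-08) on the probe set used, whereas the mean of its 3 probe sets rose by 0.79 (adjusted p = 0.00062). Gli1 was lower by 3.44 ± 0.27 and Mycl by 1.31 ± 0.36 (adjusted p = 0.012, and adjusted p = 0.055 without GFP-negative 1). Glial and immune genes were lower too, with Gdf10 at -8.48 ± 0.40 and Csf1r, the receptor microglia depend on, at -4.14 ± 0.34. With an estimated correlation the astroglia (adjusted p = 0.13), oligodendrocyte (adjusted p = 0.45) and microglia lists (adjusted p = 0.13) lost their calls. Myc (-1.06 ± 0.74), Atoh1 (0.54 ± 0.52), Ptch1 (-1.42 ± 0.89) and Cdkn2c (0.17 ± 0.10) did not pass; without Myc primary 2 the direction of Myc turned (0.10).

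The largest rises were Ppp1r14a (6.06 ± 0.35), Tex14 (5.41 ± 0.56), Ptger3 (5.23 ± 0.65), Nefh (5.16 ± 0.37), Mgp (5.08 ± 0.74) and Nrn1 (5.04 ± 0.61). After Gdf10 the largest falls were the neural genes Tfap2b (-7.06 ± 0.31), Ptf1a (-6.91 ± 0.23), the glutamate receptor genes Grm3 (-6.77 ± 0.22) and Gria1 (-6.76 ± 0.16), and Egfr, the epidermal growth factor receptor (-6.17 ± 0.44). For all of these rises except Mgp the GFP-negative mean lay below background, and for all of these falls the Myc mean did. Those sizes are set by the floor of the array. Over the Myc targets the median was 2.06 (32 of 32 rose adjusted over the list alone; adjusted p = 5.7e-21, and adjusted p = 0.099 with an estimated correlation). Cell cycle genes rose in 21 of 27 cases (22 adjusted over the list alone). The median was 0.83 (adjusted p = 3.2e-05, and adjusted p = 0.35 with an estimated correlation), with the replication licensing gene Cdt1 at 1.39 ± 0.13. Glycolysis and hypoxia genes rose in 8 of 16 cases (8 adjusted over the list alone). The median was 1.07 (adjusted p = 0.0036, and adjusted p = 0.45 with an estimated correlation), with Pfkp, phosphofructokinase, at 2.56 ± 0.31. Npr3 rose by 4.45 ± 0.61 among 4 human group 3 markers, a list that was not called (2 rose, adjusted p = 0.34).

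Shh pathway genes fell in 8 of 11 cases and rose in 1 (8 and 1 adjusted over the list alone). The median was -1.42 (adjusted p = 0.00016, and adjusted p = 0.13 with an estimated correlation), with Boc at -1.51 ± 0.26. Astroglia genes fell in 13 of 14 cases (13 adjusted over the list alone). The median was -3.06 (adjusted p = 2e-08, and adjusted p = 0.13 with an estimated correlation), with the glutamate transporter gene Slc1a3 at -3.05 ± 0.26. Microglia and macrophage genes fell in 15 of 15 cases (15 adjusted over the list alone). The median was -3.85 (adjusted p = 1.6e-13, and adjusted p = 0.13 with an estimated correlation). Oligodendrocyte lineage genes fell in 8 of 11 cases (8 adjusted over the list alone). The median was -3.07 (adjusted p = 0.0011, and adjusted p = 0.45 with an estimated correlation), with Mag at -3.65 ± 0.80 (adjusted p = 0.06 on only the 6 arrays), and all 11 were highest in Myc primary 3 within its group. Immediate early and stress genes fell in 10 of 13 cases (12 adjusted over the list alone). The median was -1.90 (adjusted p = 4.2e-05, and adjusted p = 0.35 with an estimated correlation), with Fos at -1.73 ± 0.37. Notch genes gave 5 falls and 2 rises among 11 (6 and 2 adjusted over the list alone). The median was -0.98 (adjusted p = 0.022, and adjusted p = 0.35 with an estimated correlation), with Notch1 at -3.34 ± 0.45 and the rise of Notch2 below background in both groups; cyclic loess ended the call (adjusted p = 0.062).

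Human Shh markers fell in 4 of 5 cases (4 adjusted over the list alone). The median was -3.57 (adjusted p = 0.0053, and adjusted p = 0.17 with an estimated correlation), with Pdlim3 at -4.69 ± 0.68. Human WNT markers fell in 3 of 5 cases (3 adjusted over the list alone). The median was -3.23 (adjusted p = 0.0024, and adjusted p = 0.099 with an estimated correlation), with Tnc at -5.49 ± 0.46. Neural stem cell genes gave 6 falls and 1 rise among 14 (6 and 1 adjusted over the list alone). The median was -0.41 (adjusted p = 0.026, and adjusted p = 0.13 with an estimated correlation), with Sox9 at -2.54 ± 0.25; the call ended without GFP-negative 3 (-0.45). GABAergic and Purkinje genes gave 4 falls and 2 rises among 12 (4 and 2 adjusted over the list alone). The median was -0.12, and 0.09 on centred arrays (adjusted p = 0.038, and adjusted p = 0.35 with an estimated correlation), with Gad1, the GABA-synthesising enzyme, at -4.86 ± 0.30; the call ended without Myc primary 2 (-0.09) or GFP-negative 3 (-0.10). Endothelial and mural genes gave 6 falls and 1 rise among 14 (6 and 1 adjusted over the list alone). The median was -0.50 (adjusted p = 0.025, and adjusted p = 0.71 with an estimated correlation), with Kdr, a VEGF receptor, at -2.31 ± 0.35; the call ended without Myc primary 1 (-0.31), Myc primary 2 (-0.35) or GFP-negative 2 (-0.17). Granule neuron genes gave 6 rises and 3 falls among 16 (adjusted p = 0.72), with Neurod1 at 2.94 ± 0.42. Signs differed between median and mean or test for pluripotency (0.13 and mean -0.12), human group 4 (0.24, test down) and p53 target genes (0.37 and mean -0.01). Of all genes 5772 changed, 3260 higher and 2512 lower, 3613 at least 2-fold (1868 higher and 1745 lower), with 7164 at an unadjusted p below 0.05 and 40.9% not overlapping, against 10% by chance. The share higher was 56.5%, against 43.5% with cyclic loess and 67.8% on centred arrays, where the median of all genes was 0.26, against 0.05.

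Against GFP-positive cells, the Myc primary tumours had higher Myc target and lower Shh pathway genes, and here granule lineage genes were lower too. Srm rose by 2.71 ± 0.21 (12.01 ± 0.01 against 9.30 ± 0.09, SD, n = 3; adjusted p = 2.5e-06) and Slc19a1, a folate carrier, by 2.89 ± 0.24. Mycn fell by 6.08 ± 0.20 (adjusted p = 8.7e-09) on the probe set used, whereas 1 of its 3 probe sets was called higher and their mean gave -0.20 (adjusted p = 0.35). Gli1 fell by 4.39 ± 0.27, Atoh1 by 4.30 ± 0.52 and Barhl1 by 4.88 ± 0.22. Cd44, a cell surface receptor for hyaluronan, rose by 4.66 ± 0.41, Npr3 by 4.42 ± 0.61 and Pdk1 by 4.92 ± 0.38. Mycl fell by 1.28 ± 0.36 (adjusted p = 0.019, and adjusted p = 0.067 without GFP-positive 2), while Myc (0.39 ± 0.74), Ptch1 (-1.17 ± 0.89) and Cdkn2c (0.12 ± 0.10) did not pass. Without Myc primary 2 the Myc difference was 1.56 and passed (adjusted p = 0.013).

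The largest rises were the metallothionein Mt1 (6.84 ± 0.59), Mgp (6.34 ± 0.74), Igfbp2 (5.86 ± 0.41), Ifitm3, an antiviral membrane protein (5.86 ± 0.26), Rgs5 of pericytes (5.41 ± 0.66) and Ptger3 (5.37 ± 0.65). The largest falls were Cadps2 (-6.48 ± 0.51), Mycn, Sfrp1 (-5.85 ± 0.25), Gad1 (-5.75 ± 0.30), Tfap2b (-5.52 ± 0.31) and Alcam, an adhesion molecule (-5.02 ± 0.34). For Mgp, Ifitm3, Rgs5 and Ptger3 the GFP-positive mean lay below background, and for Mycn, Gad1 and Tfap2b the Myc mean did. Those sizes are set by the floor of the array. Calls held with an estimated correlation for 4 lists: Myc targets (30 of 32 rose, 30 adjusted over the list alone; median 1.71, adjusted p = 1.1e-22), the Shh pathway (7 of 11 fell, 7 adjusted over the list alone; median -1.43, adjusted p = 1.3e-07), granule neuron progenitors (8 of 9 fell, 8 adjusted over the list alone; median -2.74, adjusted p = 6.7e-08) and granule neurons (11 of 16 fell, 11 adjusted over the list alone; median -1.39, adjusted p = 1.7e-07). For each the adjusted p was 0.025 with an estimated correlation. Members of the granule lists were Zic2 (-3.50 ± 0.34), Zic5 (-2.02 ± 0.25) and Unc5c, a netrin receptor (-4.73 ± 0.55).

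Glycolysis and hypoxia genes rose in 13 of 16 cases (15 adjusted over the list alone). The median was 2.19 (adjusted p = 2.3e-08, and adjusted p = 0.18 with an estimated correlation), with Aldoa, aldolase, at 2.43 ± 0.30. Microglia and macrophage genes rose in 9 of 15 cases (12 adjusted over the list alone). The median was 2.23 (adjusted p = 1.7e-06, and adjusted p = 0.37 with an estimated correlation), with C1qb at 3.94 ± 0.34. Endothelial and mural genes rose in 5 of 14 cases (7 adjusted over the list alone). The median was 1.03 (adjusted p = 0.00019, and adjusted p = 0.47 with an estimated correlation), with Vwf at 2.76 ± 0.41 (1.39 with the run term, which ended its call); without Myc primary 3 the median was 0.55. Fibroblast and meningeal genes rose in 6 of 10 cases (7 adjusted over the list alone). The median was 1.95 (adjusted p = 0.0005, and adjusted p = 0.37 with an estimated correlation), with Col3a1 at 4.82 ± 0.66; 9 of the 10 markers were highest in Myc primary 3 within its group, and without it the median was 1.14. Interferon and MHC class I genes rose in 8 of 13 cases (9 adjusted over the list alone). The median was 0.98 (adjusted p = 0.0009, and adjusted p = 0.37 with an estimated correlation), with the MHC gene H2-K1 at 2.59 ± 0.40. Astroglia genes rose in 6 of 14 cases (8 adjusted over the list alone). The median was 1.46 (adjusted p = 0.018, and adjusted p = 0.53 with an estimated correlation), with Apoe at 4.21 ± 0.40; the median was 0.87 without Myc primary 3 (adjusted p = 0.082). GABAergic and Purkinje genes gave 6 falls and 1 rise among 12 (7 and 1 adjusted over the list alone). The median was -0.82 (adjusted p = 0.0009, and adjusted p = 0.18 with an estimated correlation), with Lhx5 at -4.01 ± 0.24. Human Shh markers fell in 2 of 5 cases (2 adjusted over the list alone). The median was -1.37 (adjusted p = 0.012, and adjusted p = 0.24 with an estimated correlation), a call that ended without Myc primary 2 (-0.47). Of 27 cell cycle genes 3 rose and 4 fell (adjusted p = 0.37), with Mki67 at -1.03 ± 0.21. Gad2, Oasl2 and Car9 were among the called members that lay below background in both groups.

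Here 4232 genes changed, 2476 higher and 1756 lower in the Myc tumours, 2567 at least 2-fold (1522 higher and 1045 lower), with 5895 at an unadjusted p below 0.05 and 46.2% not overlapping, against 10% by chance. Median and mean or test differed in sign for forebrain neuron (0.07, test down), erythroid (0.10 and mean -0.12) and sex-linked genes (0.03 and mean -0.62). The 2 groups lie wholly in different runs of title numbers, and the run term, estimated from GFP-negative 3 alone, kept 1500 of the 4232 calls (2872 called). On centred arrays, where the median of all genes was -0.24 against 0.06, 36.4% of the changed genes were higher, against 58.5%.

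The Shh tumours were compared with GFP-positive cells, the population that holds the granule neuron progenitors. Some Shh pathway genes were higher in the tumours, while the list was not called (adjusted p = 0.11): Gli1 rose by 1.39 ± 0.27 (9.34 ± 0.27 against 7.95 ± 0.27, SD, n = 3; adjusted p = 0.0075), Hhip by 3.73 ± 0.67 and Ccnd1, cyclin D1, by 1.32 ± 0.22 (adjusted p = 0.0034). Mycn (0.08 ± 0.20), Atoh1 (0.81 ± 0.52), Myc (1.35 ± 0.74), Mycl (0.33 ± 0.36) and Cdkn2c (-0.10 ± 0.10) did not pass. Ptch1 fell by 3.34 ± 0.89 (7.16 ± 2.67 against 10.50 ± 0.19; adjusted p = 0.039), a difference of -2.04 without Shh 3 (adjusted p = 0.072); its call also ended without Shh 2 (-3.27) or GFP-positive 1 (-3.25), 2 (-3.33) or 3 (-3.44). Among microglial, astroglial and interferon genes C1qb rose by 3.94 ± 0.34, Apoe by 3.54 ± 0.40 and Oasl2 by 2.99 ± 0.26. With an estimated correlation these 3 lists had an adjusted p = 0.25, 0.35 and 0.15 and lost their calls. The run term, estimated from GFP-negative 3 alone, ended the calls of Gli1 (0.57), Hhip (3.40), Ccnd1 (1.58), Cd44 (2.46), Nop56 (0.60), Rsad2 (4.79), Nr4a1 (2.58), Hes1 (2.24), Unc5c (-2.99), Grin2b (-0.92) and Eomes (-3.42).

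The largest rises were the interferon-induced Ifi27 (5.24 ± 0.35), the keratin gene Krt12 (5.12 ± 1.42), Zc3hav1, an antiviral factor (5.09 ± 0.39), Dcpp3 (4.92 ± 0.88), Tecta (4.70 ± 0.37) and Cxcl10 (4.69 ± 0.57). For all of these rises the GFP-positive mean lay below background, so their sizes are set by the floor of the array. Krt12 read 10.44, 11.26 and 3.36 in Shh 1, 2 and 3, and its call (adjusted p = 0.046) ended without Shh 1 (4.08), Shh 2 (3.67) or GFP-positive 1 (5.08), 2 (5.19) or 3 (5.10). The largest falls were Arhgap6 (-5.95 ± 0.64), Gad1 (-5.64 ± 0.30), Tfap2b (-5.43 ± 0.31), Nefl, the light neurofilament (-4.57 ± 1.04), Tfap2a (-4.48 ± 0.28) and the peptide transporter gene Slc15a2 (-4.31 ± 0.94). For Arhgap6, Gad1, Tfap2b and Tfap2a the Shh group mean lay below background, so these sizes are set by the floor too. The calls of Nefl and Slc15a2 ended without Shh 1 (-4.09 and -3.62), Shh 2 (-3.86 and -3.81), GFP-positive 1 (-4.49 and -4.39) or GFP-positive 3 (-4.47 and -4.19).

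Myc targets of ribosome biogenesis rose in 12 of 32 cases (22 adjusted over the list alone). The median was 0.69 (adjusted p = 2.3e-12, and adjusted p = 0.15 with an estimated correlation), with Nop56 at 0.88 ± 0.12. Microglia and macrophage genes rose in 9 of 15 cases (10 adjusted over the list alone). The median was 1.99 (adjusted p = 6.1e-10, and adjusted p = 0.25 with an estimated correlation), with Ctss at 4.01 ± 0.38. Interferon and MHC class I genes rose in 7 of 13 cases (9 adjusted over the list alone). The median was 2.01 (adjusted p = 4.2e-09, and adjusted p = 0.15 with an estimated correlation), with Rsad2, viperin, at 3.99 ± 0.76. Astroglia genes rose in 4 of 14 cases (5 rose and 1 fell adjusted over the list alone). The median was 1.06 (adjusted p = 0.0025, and adjusted p = 0.35 with an estimated correlation). Neural stem cell genes rose in 3 of 14 cases (6 adjusted over the list alone). The median was 0.80 (adjusted p = 0.0043, and adjusted p = 0.15 with an estimated correlation), namely Lhx2 (3.64 ± 0.51), Cd44 (2.78 ± 0.41) and Sox9 (1.43 ± 0.25). Immediate early and stress genes gave 1 rise among 13, Nr4a1 at 2.82 ± 0.46 (5 adjusted over the list alone). The median was 0.99 (adjusted p = 0.0051, and adjusted p = 0.45 with an estimated correlation), a call that ended without Shh 2 (0.49). Endothelial and mural genes gave 1 rise among 14 (1 adjusted over the list alone). The median was 0.51 (adjusted p = 0.028, and adjusted p = 0.67 with an estimated correlation), which ended without Shh 3 (0.42) or GFP-positive 1 (0.41). Notch genes rose in 3 of 11 cases (4 adjusted over the list alone). The median was 0.25, and -0.04 on centred arrays (adjusted p = 0.047, and adjusted p = 0.43 with an estimated correlation), with Hes1 at 2.28 ± 0.46; the call ended without Shh 2 (0.28), Shh 3 (0.12) or GFP-positive 1 (0.25). Human Shh markers rose in 2 of 5 cases (3 adjusted over the list alone). The median was 0.81 (adjusted p = 0.02, and adjusted p = 0.26 with an estimated correlation).

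GABAergic and Purkinje genes gave 5 falls and 2 rises among 12 (5 and 2 adjusted over the list alone). The median was -0.55 (adjusted p = 0.0013, and adjusted p = 0.15 with an estimated correlation), with Lhx5 at -4.12 ± 0.24 and Slc32a1, the vesicular GABA transporter, at -2.66 ± 0.31; Gad2, among the falls, lay below background in both groups. Granule neuron genes gave 4 falls and 1 rise among 16 (6 and 2 adjusted over the list alone). The median was -0.64 (adjusted p = 0.02, and adjusted p = 0.26 with an estimated correlation), with Unc5c at -2.91 ± 0.55 and the glutamate receptor gene Grin2b at -1.50 ± 0.24; the call ended without Shh 3 (-0.45). Human group 4 markers gave 1 fall among 5, Eomes at -2.69 ± 0.61 (1 adjusted over the list alone). The median was -0.86 (adjusted p = 0.027, and adjusted p = 0.15 with an estimated correlation), a call that ended without Shh 2 (-0.53). As a list the Shh pathway was not called (3 rose and 1 fell of 11, adjusted p = 0.11). Median and mean or test differed in sign for erythroid (0.02, test down), pluripotency (-0.02 and mean 0.16), human group 3 (-0.03 and mean 0.31) and human WNT markers (0.14 and mean -0.47). In all 1292 genes changed, 792 higher and 500 lower in the Shh tumours, 817 at least 2-fold (524 higher and 293 lower), with 3509 at an unadjusted p below 0.05 and 39.6% not overlapping, against 10% by chance. The count was 665, 778 and 732 without GFP-positive 1, 2 and 3, 2747 without the 3 arrays that stood apart, 812 with the run term, of which only 232 were among the 1292, 2002 with every probe set, 3148 on only the 6 arrays and 3987 with array weights. On centred arrays, where the median of all genes was -0.30 against -0.01, 32.3% of the changed genes were higher, against 61.3%.

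**Figure D3:**
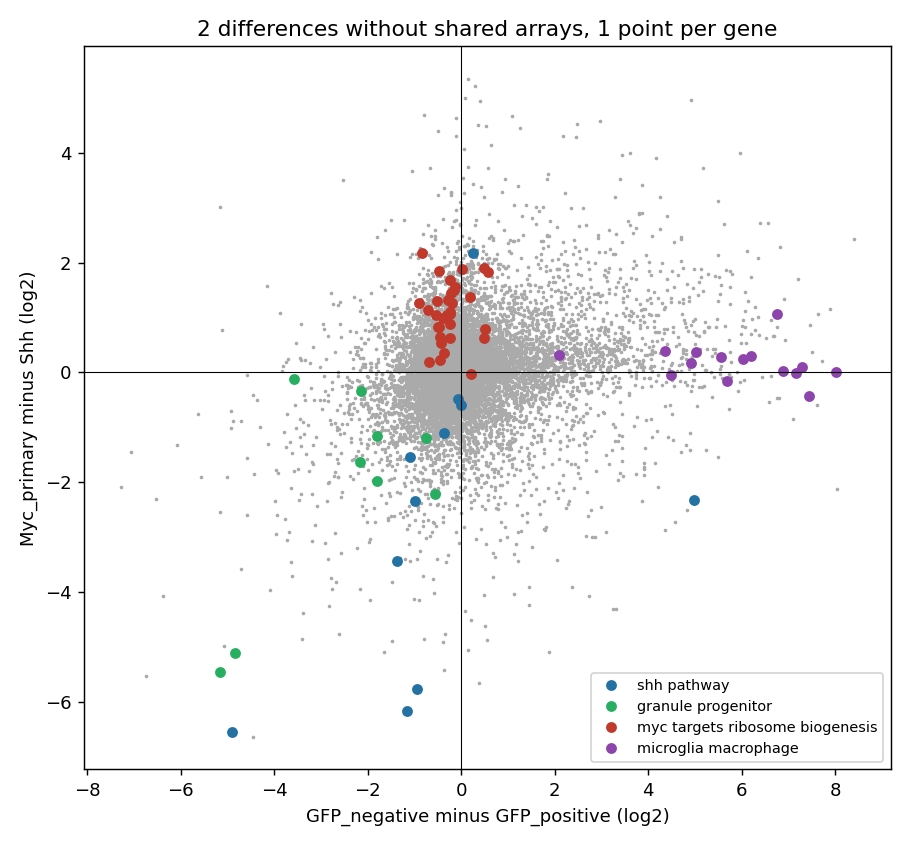
Log2 difference of Myc primary minus Shh tumours (vertical axis) against GFP-negative minus GFP-positive cells (horizontal axis), 1 point per gene, with members of 4 lists coloured. Across 17097 genes the points form a broad cloud with a Pearson correlation of 0.22.

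The last comparison asked whether the difference between Myc and Shh tumours ran along that between GFP-negative and GFP-positive cells. Genes lower in both, such as Atoh1, Barhl1 and Sfrp1, numbered 372, against 158 for independent lists, and genes higher in both numbered 281, against 199. Opposite directions were shared by 229 genes higher in Myc tumours and lower in GFP-negative cells, such as Ppp1r14a, and by 165 genes lower in Myc tumours and higher in GFP-negative cells, such as Hhip, against 182 and 173. Across genes, which are not independent replicates, Pearson's r was 0.22 and Spearman's rho 0.16. In the exact permutation of array labels within each pair of groups (400 labellings, two-sided, smallest possible p 0.01) the p-values were 0.26 and 0.28, both 0.28 adjusted over the 2 measures, and other labellings reached sizes of 0.33 and 0.25. Without Myc primary 3 the r was 0.14, and without the 3 arrays that stood apart 0.12.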

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

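All tests here except the splits of the arrays were chosen after the pattern had been seen; those of oligodendrocytes, of the Ptch1 probe set and region, and of other splits of the arrays were set down before their outcome was computed, the others after.

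The 123 genes called between Myc secondary and primary tumours, among them Rlf, Dlx1, Pou3f3 and Arhgap6, were compared on GFP-negative 3, the array of its group whose title number lies in the later run. The value of GFP-negative 3 minus the mean of GFP-negative 1 and 2, in the direction of each call, had a median of 0.25. Of 10000 matched random lists 95% lay between 0.01 and 0.22, and 95 genes (77.2%) moved in the direction of their call. This fits a shift that goes with the title numbers, of a size well below the median called difference of 1.42. It rests on 1 array, and an effect of culture or transplantation was not tested apart from it.

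Myc primary 3 had high signals of Mbp, Col3a1 and other genes of non-tumour cells. If its share of tumour cells were lower and every other cell type raised alike, microglia and macrophage markers would rise with the myelin genes; their median difference from the other 2 arrays was 0.07, against 3.80 for the oligodendrocyte lineage, which argues against that explanation. For 16 further myelin genes, such as Mal (8.74 against 5.55 and 4.15), the median was 2.05, above the upper bound of 0.24 for random lists, and 15 were higher than on both other arrays. Oligodendrocytes mixed into the sample would give such a rise. The further genes belong to the same cell type as the listed ones, which were already high on this array. Their rise was thus nearly given and does not decide whether oligodendrocytes were mixed in. Fibroblast and meningeal markers (2.52), endothelial and mural markers (1.44), immediate early genes (1.91) and astroglia (0.99) were raised too, while interferon (-0.78) and forebrain neuron genes (-0.05) were not.

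Ptch1, picked for weighing after its values had been seen, read 4.56 in Shh 3 against 9.90 and 7.03 in Shh 1 and 2. A fault of 1 probe set was left undecided: the only other probe set gave a difference of -0.01 but read below background on the Shh arrays. A weaker Shh pathway was not seen, since 10 other pathway genes had a median difference of 0.14. The 20 genes nearest to Ptch1 in GRCm38.p6, among them Fancc, had a median of 0.78 (upper bound of random lists 0.23) and of 0.08 against GFP-positive cells, which argues against a loss across all 20; Shh 1 and 2 themselves lay at -0.32 there, and Aopep (-1.99), Prxl2c (-2.37) and Cdc14b (-0.92) were lower in Shh 3, so a smaller loss or one of Ptch1 alone stayed open. Before Ptch1, the low Myc signal of Myc primary 2 had been tested in its place (-3.49 from the mean of the other 2 arrays) and was replaced after its outcome was seen: Myc targets on that array differed by a median of 0.01.

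Each comparison was repeated for the 10 ways to split its 6 arrays into 3 and 3, and in each 1 of 10 splits, the real grouping, gave as many called genes as the real grouping. Between Myc primary and Shh tumours, where Mycn and Gli1 were called, the real count was 2701 and the highest other 3 (1036 at an unadjusted p below 0.05 in limma). For Myc secondary against primary tumours the counts were 123 and 71 (2137 and 1719 unadjusted), for GFP-positive against GFP-negative cells 4505 and 0 (1489 unadjusted), and for Myc primary tumours against GFP-negative cells 5772 and 105 (2893 unadjusted). Against GFP-positive cells they were 4232 and 0 (436 unadjusted) for Myc primary tumours and 1292 and 1 (369 unadjusted) for Shh tumours. With 10 splits no share under 0.05 can be reached. Every other split mixes the 2 groups, so a difference between them widens the spread within the split groups and lowers the count. The gap between the real and the other counts is therefore partly built in.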

How the results depend on the processing

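The settings that left out 3 arrays standing apart or added a term for the run of title numbers, estimated from GFP-negative 3 alone, were chosen after the data had been seen; the rest were fixed before.

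Calls of Gli1, Mycn, Atoh1 and other named genes were kept in 6209 repeats, ended in 542, among them Mycn between Myc primary and Shh tumours (-0.29 with the mean of its probe sets), and reversed in 1: Mycn between Myc primary tumours and GFP-negative cells, 0.79 with the mean of its probe sets. With every probe set tested, a named gene was read on the same probe set as in the main fit. The 422 calls kept in that setting could therefore hardly change and say little. Of the repeats of called lists 724 kept the call and 116 did not. With an estimated correlation only 9 list calls were kept and 61 were lost, so most list calls depended on the preset correlation of 0.01.

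Between Myc primary and Shh tumours the count of 2701 ran from 1795 without Shh 2 to 2333 without Myc primary 2, and was 4073 without the 3 arrays.

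Between secondary and primary tumours, where Dlx1 was called, 123 genes (95 at least 2-fold) became 264 with means of probe sets, 426 (305) with every probe set, 274 (199) on centred arrays, 1 (1) on 6 arrays, 581 (334) with weights, 284 (170) without the 3 arrays and 860 (654) with the run term. With 1 array left out it ran from 25 (23), without Myc secondary 2, to 271 (220), without Myc primary 1.

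Between the sorted cells 4505 became 9128 on centred arrays (4236 at least 2-fold) and 7225 with weights.

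For Shh tumours against GFP-positive cells 1292 (817) became 2002 (1256) with every probe set, 3148 on 6 arrays, 3987 (1237) with weights, 2747 without the 3 arrays and 812 with the run term, and ran from 665 (518), without GFP-positive 1, to 944 (702), without Shh 1.

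The correlation of the 2 differences, 0.22, ran from 0.14 without Myc primary 3 to 0.26 without Myc primary 2 and was 0.12 without the 3 arrays.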

Other observations

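All groupings and tests here were chosen after the values had been seen, and more gene families were looked at than are given; the test of chromosome segments was set down before its outcome was computed, that of a whole copy of chromosome 13 after.

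Myc primary tumours had 427 genes higher and 228 lower than each of Shh tumours, GFP-negative and GFP-positive cells. Among the higher ones, by the difference from the nearest group, were Ptger3 (5.23), Tff3, a trefoil peptide (4.21), Lamp5, Hapln4 (3.68), the iron-binding lipocalin Lcn2 (3.40), Syt4 (3.29), the homeobox gene Lhx8 (3.27), Igfbp3 (3.05) and Trim71, an RNA-binding regulator of early development (2.97). Among the lower ones were Egfr (-4.24), Alcam (-4.12), Mdk (-4.04), the netrin receptor Dcc (-4.01), Ptprd (-2.84) and Pcdh9 (-2.26). Between Myc secondary and primary tumours 12 of the 427 and 11 of the 228 were called. Both shares were larger than that over all genes, 123 of 17097 (0.719%). The sets were chosen on their Myc primary values, which also enter that comparison. For 366 of the 427 (85.7%) and 206 of the 228 (90.4%), all 3 Myc secondary arrays lay beyond the 9 arrays of the other groups. Those 9 arrays had entered the choice of the sets, whereas the Myc secondary arrays had not.

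Between Myc primary and Shh tumours several gene families were called, and none kept its call with an estimated correlation. Mitochondrial ribosomal proteins gave 33 rises and 1 fall among 73 (median 0.53, adjusted p = 1.7e-13, and adjusted p = 0.21 with an estimated correlation), and RNA polymerase subunits 11 rises among 24 (median 0.56, adjusted p = 3.5e-06, and adjusted p = 0.19 with an estimated correlation). Complex I subunits gave 12 rises among 42 (median 0.35, adjusted p = 3.5e-06, and adjusted p = 0.3 with an estimated correlation). Cytosolic ribosomal proteins gave 6 rises and 1 fall among 77 (median 0.07, adjusted p = 0.043, and adjusted p = 0.38 with an estimated correlation). Protocadherins, adhesion molecules of neurons, fell in 14 of 36 cases (median -0.52, adjusted p = 1.9e-07, and adjusted p = 0.11 with an estimated correlation). Of 37 Hox genes 0 passed in limma (adjusted p = 0.32).

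Genes of chromosomes 13, 14 and 16 read lower as groups on many tumour arrays than in GFP-positive cells, a pattern noticed while the neighbours of Ptch1 were tested. Medians for chromosome 14 were -0.86, -0.17 and -0.60 in Myc primary 1, 2 and 3 and -0.70, -0.85 and -0.83 in Myc secondary 1, 2 and 3. Chromosome 13 gave -0.63, -0.51 and -0.36 in Shh 1, 2 and 3, and chromosome 16 gave -0.72, -0.78 and -0.23 in Myc primary, -0.77, -0.50 and -0.00 in Shh and -0.07, -0.66 and -0.60 in Myc secondary tumours. Single arrays stood out on other chromosomes, with chromosome 7 at -0.37 in Myc secondary 1 and -0.30 in Shh 3 and chromosome 4 at 0.28 in Shh 3. The largest size on autosomes of the sorted cells was 0.18. These values may reflect loss of a chromosome copy in many tumour cells. The segments tested were 4 each of chromosome 13 in Shh, 14 in Myc primary, 14 in Myc secondary and 16 in Myc primary tumours. Of these 16 segments 15 lay below the lower bound of matched random lists, against 0 of 12 in GFP-negative cells. The rule of this test left the loss undecided. These chromosomes and groups had been picked for low medians on the same arrays, unlike the GFP-negative cells. Low segments were thus largely given by the choice and do not count for a loss. They show only that the lower signal was not confined to 1 part of a chromosome. Chromosome 16 in Shh and Myc secondary tumours was not tested in segments. The segment that was not low, the first of chromosome 13 in Shh tumours, lay at 0.15, which argues against loss of a whole copy of that chromosome. DNA was not measured, and sequencing or array hybridisation of tumour DNA would test a loss.

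Krt12 read 10.44 and 11.26 in Shh 1 and 2 and 3.36 in Shh 3, the array that also had the lowest Ptch1 and the highest Xist of its group.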
